A study of Homo sapiens with 6 samples.

How the data were processed

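RNA was measured by sequencing in MCF-7 cells, a human breast adenocarcinoma line. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made by standard Illumina procedures. The 6 libraries, 3 per group, came from replicate cultures of 1 line with a lentiviral hairpin against NUDT3 (Nudt3KD) and 1 line with a hairpin that matches no mammalian gene (ConKD). The submitters' processing notes name TopHat2 2.0.9, Cuffdiff 2.2.1 and the genome build hg19. The authors deposited FPKM values (fragments mapped to a transcript, scaled by its length and by the library's mapped fragments), 1 value per RefSeq transcript and library. The annotation release, the filters and any library scaling used by Cuffdiff are not given in the sources used here.

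The table held 41138 transcripts in 6 columns, which were assigned to samples through the description in each sample's label. Accessions were paired with gene symbols through a RefSeq gene table of the assembly GRCh38.p14 (39573 transcripts) and then through GENCODE v29 (472 transcripts), which together matched 97.3% of the transcripts. The 1093 unmatched transcripts, of which 234 had a mean of at least 1 FPKM, were left out of the gene level. The reference is of another build than hg19, so it served only for names, gene order and transcript sequences, and no coordinates are given. FPKM of the transcripts of a gene were added up, which gave 22851 genes. Genes and transcripts with a mean over the 6 libraries of at least 1 FPKM were tested (11268 genes and 15484 transcripts).

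The groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes on this scale understate the change of genes at low FPKM. No count model was used, since the values are not counts. Gene lists (33) were fixed before the data were examined, and the 30 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run beside it. The lists held 984 symbols, of which 979 were found. Single genes were also compared with exact permutation tests, for which the smallest possible p is 0.1 with 3 libraries against 3.

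The genes named were chosen by a rule set before the data were examined. NUDT3 was always named, with the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups did not overlap. Examples from a list came from its 4 members with the smallest adjusted p, and the 4 mRNAs the study followed were all named. Genes outside this rule are marked as chosen after their values were seen.

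The fit was tested on simulated data made from the real means and spreads of the 11268 genes, with 200 genes changed in each of 10 runs. It recovered 75.1% of the genes changed by 0.5 on the log2 scale, 95.7% of those changed by 1 and 98.5% of those changed by 2, and 3.7% of its calls were false. With no change planted it made 0 calls, and a list shifted by -0.25 was found in 10 of 10 runs. The noise was drawn independently for each gene. These runs therefore do not show how often genes or lists are called falsely where genes vary together. In the real data 22.4% of the genes were called, at a median size of 0.28, which is under the smallest planted change of 0.5. The rates of recovery and of false calls therefore do not describe most of the real calls. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean of at least 5 FPKM), the scaling (median-ratio, quantile and TPM-like scaling to equal sums), a replicate block, 3 other limma settings, the most abundant transcript in place of the sum, and leaving out each library. After the data were seen, fits without small RNA genes and with sums that leave out small RNAs were added.

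Read totals were not given. FPKM summed to between 568670 and 696534 per library, which is no measure of depth. In genes with a single transcript and values under 0.15 FPKM, ratios between libraries clustered where 1 fragment is set against 1 fragment, which gave relative depths of 0.743 (ConKD replicate 1), 0.877 (ConKD replicate 2), 0.831 (Nudt3KD replicate 0), 0.778 (Nudt3KD replicate 1) and 0.848 (Nudt3KD replicate 2) against ConKD replicate 0. Between 88.5% and 90.6% of these ratios lay within 5% of a ratio of whole fragments up to 5, against 52.6% to 61.6% at random offsets. Absolute depth stays unknown, so no counting intervals are given.

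For tests on sequence, the length, GC content and 3-prime UTR of each gene's transcript were taken from GENCODE v29, and 99.1% of the tested genes had a sequence. Words of 7 bases were compared between genes with a 3-prime UTR of at least 50 bases (10433 genes) after removal of a smooth trend on UTR length and GC content, against 100 shuffles. A word planted with a change of -0.1 in simulated data was recovered. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.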

Results

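The data are FPKM of RefSeq transcripts in 6 libraries of MCF-7, a human breast adenocarcinoma line that expresses the estrogen receptor. The groups are 3 libraries of cultures with a hairpin against NUDT3 (Nudt3KD) and 3 libraries of cultures with a control hairpin (ConKD), all titled 0 h. NUDT3 is a Nudix hydrolase, and the study's title names it as an mRNA decapping enzyme with a part in cell migration. The comparison asks which mRNAs differ when NUDT3 is reduced. Each group is 1 stably transformed line with 1 hairpin, so p-values measure the spread between cultures, and a difference between the lines cannot be told apart from the reduction of NUDT3. Read totals are unknown. The median tested gene had between 10.5 and 10.8 FPKM in every library. Small RNA genes took between 3.21% and 20.3% of the summed FPKM, and this share differed widely within each group. Correlations of log2 values across genes were at least 0.965 within groups and at least 0.960 across groups; genes are not independent replicates.

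NUDT3 mRNA was reduced in every Nudt3KD library. It stood at 16.2, 19.1 and 22.2 FPKM in the ConKD libraries (19.2 ± 2.99, SD, n = 3) and at 4.51, 6.16 and 5.23 FPKM in the Nudt3KD libraries (5.30 ± 0.822, SD, n = 3). The mean was 3.62-fold lower, and the change was -1.68 ± 0.13 (SE) on the log2(FPKM + 1) scale (limma, adjusted p = 0.000369). An exact permutation test gave p = 0.1 with n = 3, the smallest this design allows. The table lists 1 transcript of this gene, NM_006703.

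**Figure D1:**
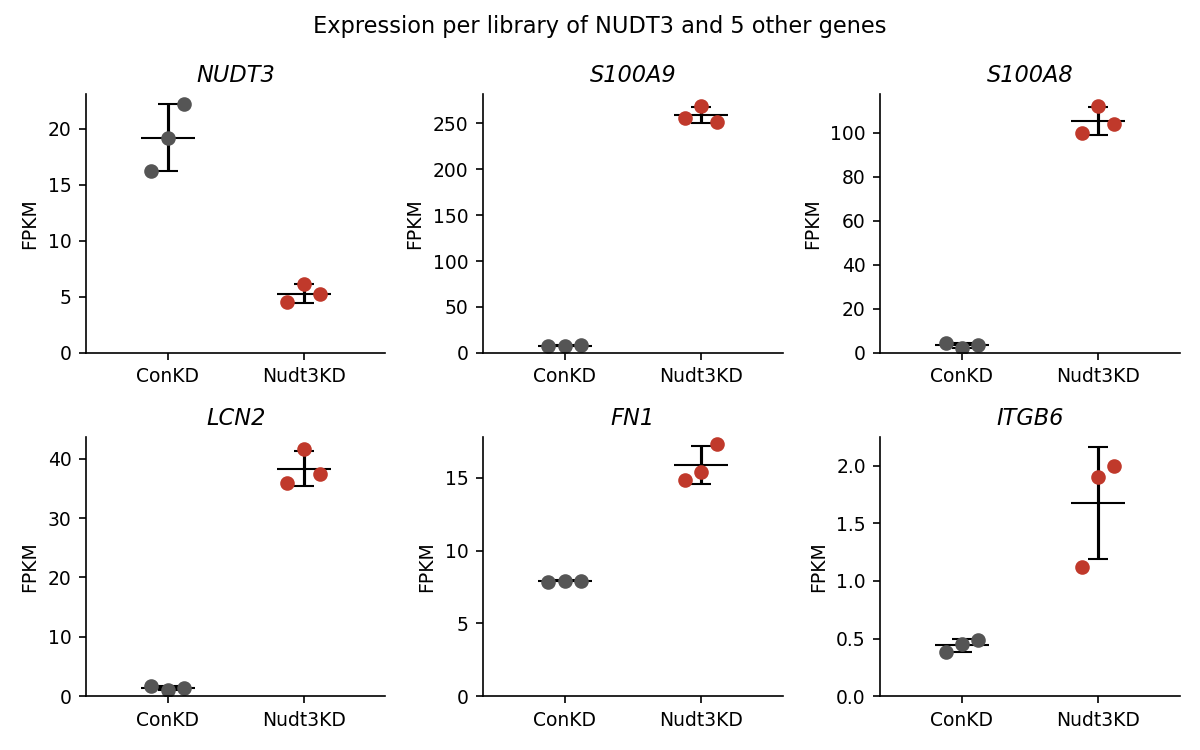
FPKM per library (y axis, linear, from 0) of NUDT3, S100A9, S100A8, LCN2, FN1 and ITGB6 in ConKD (grey) and Nudt3KD (red); each point is 1 library, and bars show the mean and SD of 3. NUDT3 lies between 16.2 and 22.2 FPKM in ConKD and between 4.51 and 6.16 in Nudt3KD, and the other 5 genes are higher in each Nudt3KD library than in any ConKD library.

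Several of the mRNAs that rose most in Nudt3KD encode secreted antimicrobial or acute-phase proteins. S100A9, a calcium-binding subunit of calprotectin, rose from 7.99 ± 0.475 to 259 ± 8.90 FPKM (SD, n = 3), which is 4.85 ± 0.05 (SE) on the log2 scale (limma, adjusted p = 8.7e-09). Its partner S100A8 rose from 3.47 ± 1.20 to 105 ± 6.31 FPKM, the iron-siderophore binder LCN2 from 1.40 ± 0.398 to 38.3 ± 2.91 FPKM, and the antimicrobial S100A7 from 0.066 ± 0.114 to 15.5 ± 3.24 FPKM. The protease inhibitor SERPINA3 rose from 16.4 ± 1.12 to 98.6 ± 3.98 FPKM, the protease inhibitor SLPI from 0.977 ± 0.674 to 6.81 ± 0.759 FPKM, and the complement factor CFB from 0.030 ± 0.033 to 2.19 ± 0.430 FPKM. The acute-phase gene SAA1 was listed at 0 in the 3 ConKD libraries and at 5.57, 4.20 and 3.92 FPKM in the Nudt3KD libraries. CLEC3A, a lectin of cartilage, rose from 0.915 ± 0.211 to 5.92 ± 0.287 FPKM, and the potassium channel KCNK2 from 2.11 ± 0.113 to 8.58 ± 0.786 FPKM. AKR1C1, an aldo-keto reductase of steroid metabolism, rose from 1.52 ± 0.395 to 6.42 ± 0.382 FPKM. AKR1C1, SAA1 and S100A7 have near-identical paralogs, so their fragments may be split between copies. Adjusted p for the genes of this paragraph lay between 8.7e-09 and 0.00169 (limma).

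The mRNAs that fell most after NUDT3 included transporters and a glycosyltransferase. The sulfate transporter SLC26A2 fell from 11.04 ± 0.068 to 4.24 ± 0.349 FPKM (SD, n = 3), which is -1.20 ± 0.06 (SE) on the log2 scale (limma, adjusted p = 9.19e-05). The sodium/calcium exchanger SLC24A3 fell from 2.65 ± 0.142 to 0.674 ± 0.096 FPKM, and GALNT12, an enzyme that starts mucin-type O-glycosylation, from 2.67 ± 0.146 to 0.751 ± 0.054 FPKM. TARP, a transcript of the T cell receptor gamma locus, fell from 10.1 ± 0.909 to 4.11 ± 0.686 FPKM, and it overlaps other genes there. The zinc finger gene UNKL fell from 7.32 ± 1.79 to 3.34 ± 1.20 FPKM, a call that was lost without ConKD replicate 0 (adjusted p = 0.086), ConKD replicate 1 (0.0577) or Nudt3KD replicate 0 (0.0509). It was also lost with no filter (0.0576), with robust moderation in limma (0.0622) and with the most abundant transcript (0.0561).

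Small nucleolar RNAs made up 7 of the 24 largest changes. SNORA25 and SNORA44 were listed at 0 in the 3 Nudt3KD libraries and at 15.6 to 30.7 and 10.2 to 39.9 FPKM in the ConKD libraries. SNORA24, SNORA4, SNORA2A and SNORA61 also passed the threshold as lower and SNORA72 as higher, with adjusted p between 0.0271 and 0.0499 (limma). Values of these 7 RNAs lay within 1.5% of whole multiples of the value of 1 fragment and stood for at most 8 fragments in a library. For these short RNAs that value differed between libraries otherwise than the relative depths given above. The fragment numbers are therefore inferred from FPKM and not read counts. The calls of SNORA24, SNORA4, SNORA2A, SNORA61 and SNORA72 were lost in at least 4 of the 6 fits that leave out 1 library each. For example, the adjusted p of SNORA4 was 0.108 without ConKD replicate 0.

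Over all 11268 tested genes, 957 were higher and 1571 lower in Nudt3KD (limma, adjusted p under 0.05), 22.4% of the genes. Most changes were small. Among the called genes the median size was 0.28 on the log2 scale, 34 genes rose and 11 fell by at least 1 on the log2(FPKM + 1) scale. The groups did not overlap for 42.2% of the genes, against 10% by chance. The count of calls depended on single libraries, falling to 1351 without ConKD replicate 0, 1621 without ConKD replicate 1, 952 without Nudt3KD replicate 0 and 1224 without Nudt3KD replicate 1. The balance of directions depended on scaling: 37.9% of the calls were higher as deposited, 48.8% after quantile scaling and 49.4% after scaling to sums without small RNAs. Median-ratio scaling gave 1090 higher and 1089 lower genes, and TPM-like scaling gave 553 higher and 164 lower. Taking the most abundant transcript of each gene in place of the sum gave 1425 calls, and a replicate block gave 1028.

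**Figure D2:**
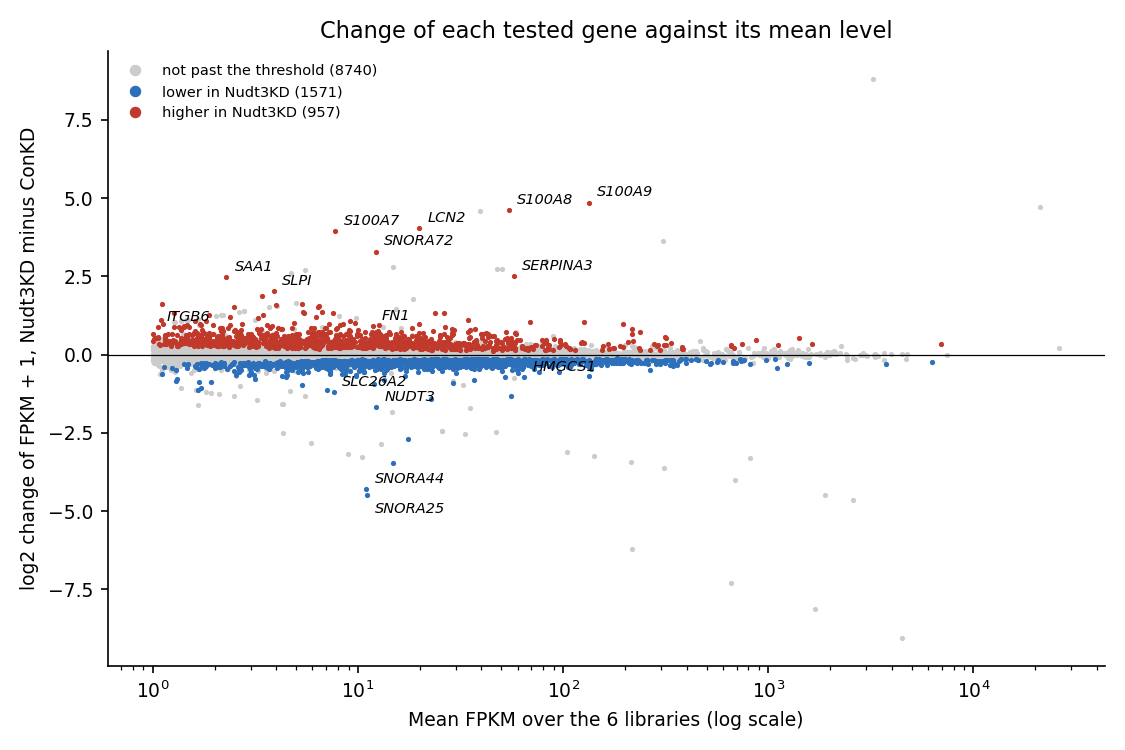
Change of each tested gene on the log2(FPKM + 1) scale (y axis) against its mean FPKM over the 6 libraries (x axis, log scale); points are genes, red for the 957 higher, blue for the 1571 lower and grey for the rest. The largest rises past the threshold are S100A9 (4.85), S100A8 (4.61) and LCN2 (4.05), and NUDT3 lies at -1.68.

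Inflammation genes and S100 genes rose as groups. Of 14 tested NF-kB targets and acute-phase genes, 10 were higher, 1 lower and 3 did not pass the test (12 higher and 1 lower adjusted over the list alone), with S100A9, LCN2, S100A8 and SAA1 as leading members (camera, adjusted p = 3.09e-11; adjusted p = 0.0573 with an estimated correlation). Of 10 S100 genes, 6 were higher and 2 lower, the same counts as adjusted over the list alone (camera, adjusted p = 4.84e-05; adjusted p = 0.185 with an estimated correlation). Besides S100A7, S100A8 and S100A9, S100P rose from 6.13 ± 0.114 to 13.3 ± 1.79 FPKM (SD, n = 3). The type I interferon response list had 10 higher and 2 lower of 28 (11 and 3 adjusted over the list alone; camera, adjusted p = 7.38e-05; adjusted p = 0.0807 with an estimated correlation). In it the membrane protein BST2 rose from 16.9 ± 0.473 to 29.5 ± 1.43 FPKM and the ubiquitin-like modifier ISG15 from 5.74 ± 0.233 to 8.40 ± 0.650 FPKM. Across 18 leukocyte markers, of which 2 had a mean of at least 1 FPKM, the median was 0.020 FPKM in ConKD and 0.035 in Nudt3KD. The highest fibroblast marker means were those of COL1A1, at 1.07 ± 0.12 FPKM in ConKD and 1.70 ± 0.305 in Nudt3KD (SD, n = 3). Among the other fibroblast markers, COL5A1 had 0.442 ± 0.119 and 1.20 ± 0.104 FPKM, COL6A1 0.669 ± 0.051 and 1.13 ± 0.144, COL6A2 0.429 ± 0.094 and 0.881 ± 0.077, and COL3A1 0.118 ± 0.016 and 0.32 ± 0.071. These collagens were chosen after their values were seen, and the markers were not tested as a list. COL5A2 had 0.349 and 0.485 FPKM. LUM, THY1, PDGFRA, POSTN and FAP were at 0 in both groups. COL1A2, COL6A3, PDGFRB, DCN, FBN1 and BGN were at most 0.038 FPKM in either group. The highest endothelial marker, EGFL7, chosen after its values were seen, rose from 2.80 to 10.1 FPKM. Of 7 tested markers of basal epithelial cells, 2 were higher and 1 lower, over all genes and adjusted over the list alone (camera, adjusted p = 0.334), and the transcription factor TP63 rose from 1.47 ± 0.055 to 2.63 ± 0.156 FPKM.

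Among genes of adhesion and motility, the 4 mRNAs that the study followed were all higher. Besides S100A8 and LCN2, the matrix protein FN1 rose from 7.91 ± 0.035 to 15.9 ± 1.29 FPKM (SD, n = 3) and the integrin subunit ITGB6 from 0.441 ± 0.055 to 1.68 ± 0.482 FPKM (limma, adjusted p = 0.000244 and 0.00706). All 4 also passed adjusted over the list alone (camera, adjusted p = 2.17e-07; adjusted p = 0.0789 with an estimated correlation). The study chose these genes on these samples, so this list is not independent evidence of their direction. Of 16 extracellular proteases and inhibitors, 10 were higher and 1 lower, over all genes and adjusted over the list alone (camera, adjusted p = 6.33e-06; adjusted p = 0.0789 with an estimated correlation). Its leading members included the protease inhibitor TIMP2, which rose from 9.66 ± 0.517 to 15.5 ± 0.542 FPKM, and the membrane-bound protease MMP16, which fell from 2.80 ± 0.390 to 1.04 ± 0.123 FPKM. Of 14 extracellular matrix genes, 6 were higher and 2 lower, the same adjusted over the list alone (camera, adjusted p = 0.0103; adjusted p = 0.231 with an estimated correlation), and THBS1 fell from 16.2 ± 0.899 to 11.1 ± 0.362 FPKM. Of 10 integrin subunits, 4 were higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.0398; adjusted p = 0.185 with an estimated correlation). The fibronectin receptor subunit ITGA5 rose from 4.76 ± 0.243 to 9.29 ± 0.167 FPKM. The integrin call was lost without ConKD replicate 0 (adjusted p = 0.0533), ConKD replicate 1 (0.0518) or Nudt3KD replicate 2 (0.0743). It was also lost with a mean of at least 5 FPKM (0.0504) and after median-ratio scaling (0.051), quantile scaling (0.0774) or scaling to sums without small RNAs (0.0634).

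Other motility lists did not pass with camera. Actin and lamellipodium regulators had 6 higher and 5 lower of 47 (7 and 6 adjusted over the list alone; camera, adjusted p = 0.728), with the actin-severing protein GSN higher (7.03 ± 0.191 against 12.9 ± 0.287 FPKM, SD, n = 3). The tropomyosin gene TPM1 was lower (101 ± 3.06 against 76.9 ± 2.72 FPKM), a call lost after TPM-like scaling (adjusted p = 0.0889), where the change was -0.36 against -0.38 as deposited. Epithelial junction genes had 3 higher and 5 lower of 30, also adjusted over the list alone (camera, adjusted p = 0.967), and the tight junction gene CLDN1 rose from 2.13 ± 0.377 to 3.90 ± 0.128 FPKM. Mesenchymal genes had 2 higher and 1 lower of 6 (3 and 1 adjusted over the list alone; camera, adjusted p = 0.0514), and this list was past the threshold as higher with fry (adjusted p = 0.000918). TGF-beta response genes had 6 higher and 5 lower of 17 (7 and 6 adjusted over the list alone; camera, adjusted p = 0.284), among them BHLHE40, which rose from 15.1 ± 0.727 to 23.6 ± 1.30 FPKM.

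Stress and immediate early mRNAs rose together with these groups. Of 31 integrated stress response genes, 16 were higher and 1 lower (21 and 1 adjusted over the list alone; camera, adjusted p = 1.14e-10; adjusted p = 0.154 with an estimated correlation). The mTORC1 inhibitor DDIT4 rose from 44.3 ± 2.76 to 93.0 ± 5.39 FPKM (SD, n = 3), the glutathione-degrading enzyme CHAC1 from 5.38 ± 0.192 to 11.5 ± 0.855 FPKM, and the amino acid transporter subunit SLC7A5 from 252 ± 16.7 to 374 ± 7.35 FPKM. Of 30 immediate early and AU-rich mRNAs, 17 were higher and 0 lower (19 and 1 adjusted over the list alone; camera, adjusted p = 1.38e-08; adjusted p = 0.0789 with an estimated correlation). The MAP kinase phosphatase DUSP4 rose from 8.43 ± 0.409 to 16.95 ± 0.124 FPKM and IER3 from 181 ± 6.51 to 296 ± 22.0 FPKM. Hypoxia and glycolysis genes had 9 higher and 3 lower of 28, also adjusted over the list alone (camera, adjusted p = 0.000999; adjusted p = 0.199 with an estimated correlation), and the glycolytic regulator PFKFB3 rose from 16.9 ± 0.089 to 25.5 ± 1.21 FPKM. The p53 targets had 7 higher and 5 lower of 27 (8 and 6 adjusted over the list alone; camera, adjusted p = 0.366). In that list the cytokine GDF15 rose from 14.5 ± 1.64 to 38.1 ± 3.27 FPKM and the cell cycle inhibitor CDKN1A from 50.2 ± 1.85 to 69.3 ± 1.48 FPKM. With the most abundant transcript in place of the sum, the change of CDKN1A was 1.83 against 0.46 on the log2 scale and no longer past the threshold (adjusted p = 0.0567). Unfolded protein response genes had 3 higher and 3 lower of 24 (5 and 4 adjusted over the list alone; camera, adjusted p = 0.0798). This list passed the threshold with a mean of at least 5 FPKM (adjusted p = 0.0409), after quantile scaling (0.00727), after scaling to sums without small RNAs (0.0303) and without ConKD replicate 0 (0.0246).

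Genes of DNA replication, mitosis and cholesterol synthesis fell. Of 36 replication genes, 28 were lower and 0 higher (30 and 0 adjusted over the list alone), with a median of -0.24 on the log2 scale (camera, adjusted p = 2.13e-09; adjusted p = 0.0789 with an estimated correlation). The helicase subunit MCM4 fell from 69.3 ± 0.990 to 54.7 ± 1.81 FPKM (SD, n = 3) and the origin licensing factor CDC6 from 40.7 ± 0.756 to 31.9 ± 1.38 FPKM. Of 32 mitosis genes, 14 were lower and 0 higher (17 and 0 adjusted over the list alone), with a median of -0.15 (camera, adjusted p = 4.29e-05; adjusted p = 0.154 with an estimated correlation), and cyclin B1 (CCNB1) fell from 147 ± 5.02 to 119 ± 2.23 FPKM. The calls of MCM4, CDC6 and CCNB1 were lost after TPM-like scaling (adjusted p = 0.18, 0.153 and 0.256), where their changes were -0.32, -0.33 and -0.28 on the log2 scale, against -0.34, -0.34 and -0.30 as deposited. Of 27 cholesterol and sterol-regulated genes, 19 were lower and 0 higher (20 and 0 adjusted over the list alone), with a median of -0.32 (camera, adjusted p = 1.38e-08; adjusted p = 0.0573 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell from 80.8 ± 1.21 to 48.8 ± 0.874 FPKM, the squalene synthase FDFT1 from 113 ± 2.04 to 77.3 ± 1.66 FPKM, and the fatty acid desaturase SCD from 311 ± 4.37 to 219 ± 9.31 FPKM.

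**Figure D3:**
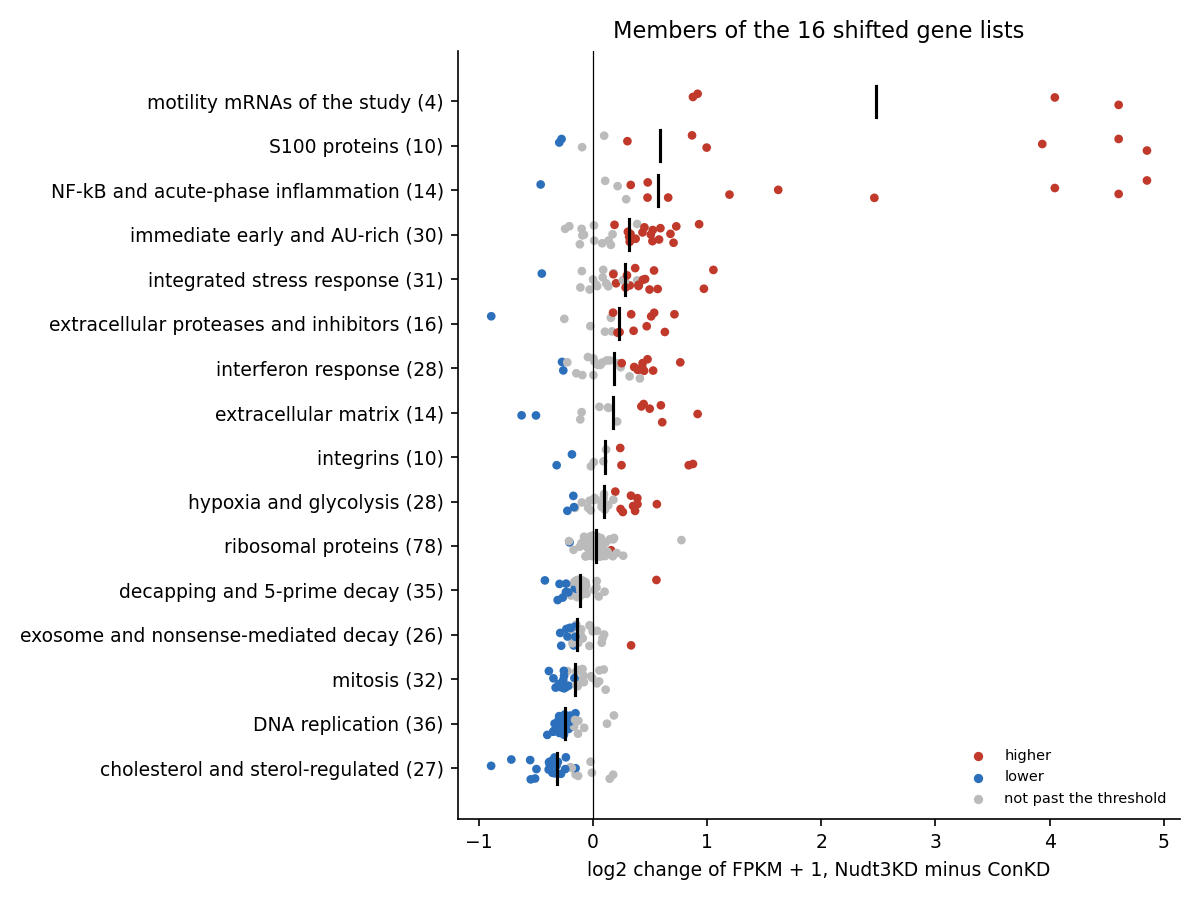
Change on the log2(FPKM + 1) scale (x axis) of each tested member of the 16 lists past the threshold (rows, number of tested members in brackets); points are genes, red if higher, blue if lower and grey if not past the threshold, spread vertically at random, and black bars are list medians. The replication (-0.24) and cholesterol (-0.32) members lie mostly below 0, and the S100 and inflammation lists carry the largest rises.

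Factors of mRNA decay were lower as groups by small amounts. Of 35 decapping, deadenylation and 5-prime decay factors, 8 were lower and 1 higher, also adjusted over the list alone (camera, adjusted p = 0.0103; adjusted p = 0.401 with an estimated correlation), a call lost after TPM-like scaling (adjusted p = 0.0681). The nuclear 5-prime exonuclease XRN2 fell from 53.5 ± 0.848 to 44.3 ± 1.58 FPKM (SD, n = 3), a call lost after TPM-like scaling (adjusted p = 0.372) at a change of -0.25 against -0.27 as deposited, and the higher member was the antiproliferative gene BTG2 (6.14 ± 0.423 against 9.49 ± 0.521 FPKM). Of 26 exosome and nonsense-mediated decay factors, 9 were lower and 1 higher (12 and 1 adjusted over the list alone; camera, adjusted p = 0.0309; adjusted p = 0.161 with an estimated correlation). That call was lost without ConKD replicate 1 (adjusted p = 0.147) or Nudt3KD replicate 2 (0.0541) and after quantile (0.0551) or TPM-like scaling (0.16), and with a mean of at least 5 FPKM (0.0673). The 20 other Nudix hydrolases had 1 higher and 1 lower, also adjusted over the list alone (camera, adjusted p = 0.967), and the lower one was NUDT15 (19.2 ± 0.654 against 15.4 ± 0.134 FPKM), a call lost after TPM-like scaling (adjusted p = 0.256) at a change of -0.29 against -0.30 as deposited. Inositol phosphate genes had 2 higher and 1 lower of 19 (1 and 1 adjusted over the list alone; camera, adjusted p = 0.967). RNAs known to be sensitive to nonsense-mediated decay had 2 higher and 2 lower of 20 (1 and 1 adjusted over the list alone; camera, adjusted p = 0.366).

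Estrogen receptor targets and luminal identity genes changed in both directions without passing as groups with camera. The mixed test of fry, which 28 of the 30 lists passed, gave them adjusted p = 9.72e-06 and 8.26e-06. The estrogen receptor targets had 10 higher and 8 lower of 31 (11 and 9 adjusted over the list alone; camera, adjusted p = 0.315). The ubiquitin ligase SIAH2 fell from 47.3 ± 1.68 to 26.4 ± 1.21 FPKM (SD, n = 3) and the transcription factor EGR3 rose from 11.9 ± 0.526 to 20.4 ± 0.684 FPKM, a call lost with the most abundant transcript (adjusted p = 0.0541; change 0.54 against 0.73). Luminal identity genes had 3 higher and 6 lower of 21, also adjusted over the list alone (camera, adjusted p = 0.811), with the mucin MUC1 higher (5.14 ± 0.179 against 8.78 ± 0.155 FPKM; change 1.33 against 0.67, adjusted p = 0.16, with the most abundant transcript) and the androgen receptor AR lower (7.53 ± 0.163 against 5.31 ± 0.236 FPKM). Ribosomal protein genes had 1 higher and 1 lower of 78 (0 and 0 adjusted over the list alone), with a median of 0.02 (camera, adjusted p = 0.0219; adjusted p = 0.816 with an estimated correlation). That call was lost without ConKD replicate 1 (adjusted p = 0.21), ConKD replicate 2 (0.0545) or Nudt3KD replicate 1 (0.399), with no filter (0.122), after TPM-like scaling (0.163) and with fry (0.705). Nuclear-encoded oxidative phosphorylation genes had 5 higher and 5 lower of 72 (1 and 2 adjusted over the list alone; camera, adjusted p = 0.549), and this list passed the threshold after quantile scaling (adjusted p = 0.00178). Replication-dependent histone mRNAs, which lack a poly(A) tail, had 0 higher and 1 lower of 16 (0 and 0 adjusted over the list alone; camera, adjusted p = 0.894). Medians and tests differed in sign for the estrogen, p53, oxidative phosphorylation, actin, inositol and Nudix lists, and the mean and the test for the epithelial junction list, none of which passed.

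Of the 30 lists tested, 11 shifted up and 5 down with the preset correlation. The 11 include the list of 4 mRNAs that the study chose on these samples, which is not independent evidence. These mRNAs are also leading members of other lists. S100A8 and LCN2 lead in the inflammation list, S100A8 in the S100 list, FN1 in the matrix list and ITGB6 in the integrin list. The inflammation and S100 lists share S100A9 as well, so these lists are not separate results. Only 14 of 35 inflammation, 10 of 18 S100, 16 of 34 protease, 14 of 36 matrix and 10 of 25 integrin genes were tested. A gene near 0 in ConKD could enter only by being higher in Nudt3KD, and the reverse held near 0 in Nudt3KD. The shares of changed members can therefore be raised by the filter. With no filter, 15 of the 16 shifted lists still passed with camera. With camera and an estimated correlation 0 passed, where the smallest adjusted p was 0.0573 and 9 lists had an unadjusted p under 0.05, and 18 passed with fry. The estimated correlation of the cholesterol list was 0.009, under the preset 0.01. A higher correlation between its members therefore does not account for the loss of that call. The estimate was also under 0.01 for the exosome (-0.02) and integrin (-0.009) lists. It was above 0.01 for the other shifted lists, for example 0.068 for replication, 0.211 for the integrated stress response and 0.533 for ribosomal proteins. For those lists a higher correlation can have contributed to the loss. In counts not adjusted for UTR length, 17.3% of the lower genes carried the 7-base word GTTGGAA in the annotated 3-prime UTR, against 6.21% of the higher genes and 10.4% of the genes not called. These shares are not independent evidence, since the word was picked in these data for going most with lower values. Among the genes named above, NUDT3, SLC26A2, HMGCS1, MMP16, SIAH2, TPM1, AKR1C1, DDIT4, TP63 and PFKFB3 carry this word.

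At the level of single transcripts, 360 were higher and 500 lower of 15484 (limma, adjusted p under 0.05). Of these, 8 had no gene symbol and the rest belonged to 825 genes, of which 761 also changed at the gene level. In 5 genes, named here after their values were seen, transcripts changed in both directions, namely KCTD15, CEP131, SEZ6L2, MELK and ATG101. In KCTD15, the transcript NM_001129994 fell from 14.3 ± 0.217 to 1.68 ± 2.19 FPKM (SD, n = 3) and NM_001129995 rose from 0.655 ± 1.09 to 14.5 ± 2.67 FPKM (limma, adjusted p = 0.0375 and 0.017), while the gene's sum was 17.9 ± 0.912 against 18.4 ± 0.578 FPKM. Transcript values depend on how fragments were assigned between overlapping models. The count of transcripts fell to between 105 and 480 when 1 library was left out, with each library moving it by over 1.5 times (169 without ConKD replicate 0, 152 without ConKD replicate 1, 480 without ConKD replicate 2, 118 without Nudt3KD replicate 0, 105 without Nudt3KD replicate 1 and 232 without Nudt3KD replicate 2). It was 55 after TPM-like scaling and 7 with a replicate block.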

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

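The fits without small RNA genes and with sums that leave out small RNAs were chosen after the data were seen, and the other alternatives before. The fall of NUDT3 kept its direction and stayed past the threshold in all 20 alternatives, between -1.84 (pseudocount 0.1) and -1.23 (pseudocount 5), and between -1.79 and -1.57 when 1 library was left out. The count of changed genes was 2528. It fell to 717 after TPM-like scaling, but was 2162 (1068 higher and 1094 lower) when the sums left out small RNAs, so that fall went with the small RNA part of the sums. It fell to 1028 with a replicate block and to 1425 with the most abundant transcript, and ranged from 952 to 2268 when 1 library was left out. The count of transcripts was 860. It fell to 55 after TPM-like scaling and to 7 with a replicate block, and ranged from 105 to 480 when 1 library was left out. Across genes, samples with the same replicate number did not deviate together (correlations of 0.117, -0.027 and 0.045). The small RNA share of the summed FPKM did follow the number. In both groups it was lowest in replicate 0 (3.21% in ConKD and 4.84% in Nudt3KD) and highest in replicate 1 (16.9% and 20.3%). Whether the numbers mark pairs therefore stays open. The count of shifted lists was 16, ranged from 13 to 16 when 1 library was left out, was 16 with the block and was 0 with an estimated correlation. Fry also passed the basal epithelial (0.00357), mesenchymal (0.000918) and p53 (0.0457) lists. The other causes were not tested.

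With the most abundant transcript in place of the sum, ESR1 (0.33) and PARN (0.07) turned from lower to higher, no longer past the threshold. The lists that changed direction did not pass in the deposited scaling. For epithelial junction genes the adjusted p in the other direction was 0.935 after median-ratio, 0.678 after TPM-like and 0.534 after quantile scaling, 0.958 with the block, 0.957 without small RNA genes and 0.807 after TPM-like scaling without small RNAs. Without 1 library the adjusted p ranged from 0.759 to 0.977, with 4 of the 6 fits in the other direction. For inositol phosphate genes it was 0.882 with no filter, 0.872 after TPM-like and 0.86 after quantile scaling and 0.188 with fry, and from 0.774 to 0.977 without 1 library (2 of 6 in the other direction). For the Nudix family it was 0.755 with no filter, 0.955 with a mean of at least 5 FPKM and 0.364 with fry, and from 0.759 to 0.959 without 1 library (3 of 6). Luminal identity genes gave 0.946 with no filter and 0.886 with fry. Oxidative phosphorylation genes gave 0.946 with no filter and 0.886 with fry, and from 0.0976 to 0.953 without 1 library (2 of 6). Replication histones gave 0.728 with a mean of at least 5 FPKM and from 0.635 to 0.902 without 1 library (1 of 6, without ConKD replicate 2). Depth is unknown in absolute terms, so the number of fragments behind genes near 1 FPKM is not known.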

Other observations

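The tests for other cell types, library scaling, small nucleolar RNAs, the action of the seed, the list members without the word and other splits of the libraries were chosen after the results were seen; those on neighbours of S100A8, length and GC content, the share of list members with the word, AU-rich words and NRF2 targets were set before their results. The margin of 1 SE asked of tests with an SE, the bound for scaling, the separate reading of mitosis genes and the runs of neighbouring genes after removal of the length and GC trend were also settled after values were seen. Genes outside the naming rule were picked here after their values were seen. Besides AKR1C1, the related steroid-metabolising enzymes AKR1C2 and AKR1C3 rose in Nudt3KD, from 1.62 ± 0.181 to 5.24 ± 0.190 and from 0.813 ± 0.123 to 4.15 ± 0.254 FPKM (SD, n = 3; limma, adjusted p = 0.000158 and 0.000123), although fragments may be split among these near-identical genes. CASP14, a protease of cornifying epidermis, rose from 2.80 ± 0.137 to 10.02 ± 0.521 FPKM, and PADI3, which citrullinates hair follicle proteins, from 2.67 ± 0.193 to 8.18 ± 0.477 FPKM. The activin subunit INHBB fell from 16.1 ± 0.898 to 7.85 ± 0.634 FPKM, the RNA-binding protein gene FMR1 from 17.3 ± 1.26 to 9.42 ± 0.487 FPKM and the receptor FGFR2 from 4.29 ± 0.468 to 2.04 ± 0.083 FPKM. AKR1C genes are known targets of NRF2, and a candidate explanation for their rise is activation of that factor. The other 23 tested NRF2 targets had a median change of -0.01 ± 0.04 (SE of the median; -0.008 unrounded), with 4 higher and 2 lower. A median under 0.05 had been set beforehand as going against NRF2 targets as a group, and this median met it. It argues against a shared rise of these targets. Members went both ways, so an activation limited to some targets stays open.

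Genes with the word GTTGGAA in the 3-prime UTR were lower in Nudt3KD, which gives a hypothesis about the hairpin. Of 15316 words of 7 bases, this word went most with lower values (z = -6.20, against -4.29 as the 5th percentile of the most extreme word in 100 shuffles), and the overlapping AGTTGGA came second (z = -4.96). The highest z, of a word that went with higher values, was 4.79, so large z values were not limited to lower genes. No shuffled limit is given for that side. The 1149 genes with GTTGGAA averaged 0.039 below the rest (-0.039) after removal of the UTR length and GC trend. Genes with 1 site averaged -0.030 ± 0.006 (SE) and genes with 2 or more sites -0.063 ± 0.014. The difference between them was -0.032 ± 0.015. The 3-prime UTR of NUDT3 carries this word, but so do 46.3% of 205 other UTRs of 7000 to 12000 bases, so its presence there decides nothing. A candidate explanation is that the NUDT3 hairpin acts on other mRNAs through its seed, as microRNAs do. It stays open, since the word was found in these data, the sequence of the hairpin was not used here and another regulator that reads the word would give the same values.

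The rise of S100A9, S100A8, LCN2, S100A7, SERPINA3, SAA1, SLPI and CFB was set against other cell types and gene dosage. Leukocytes express several of these genes, but 18 leukocyte markers differed by a median of 0.005 FPKM, 2 of them were higher in all 3 Nudt3KD libraries, and the most abundant, CORO1A, stood at 12.6 and 15.1 FPKM. Basal epithelial cells would bring basal keratins, but the summed FPKM of 6 basal keratins rose by 0.08 ± 0.06 (SE), from 0.13 to 0.20. The rise of S100A9 was 251. Other keratins were not examined, and CASP14, PADI3 and TP63 rose while the basal marker SFN fell. Squamous cells without basal keratins therefore stay open. The 20 nearest tested neighbours of S100A8 other than S100 genes had a median change of -0.117 (SE 0.043), which argues against a gain of the region; over the genome, 73 runs of 25 neighbouring genes went beyond 100 shuffles before removal of the length and GC trend and 0 after it. A response of the cells to lower NUDT3, an effect of the hairpin on another gene and a difference between the stable lines stay open, since the design has 1 line per group.

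The lower DNA replication, mitosis and cholesterol synthesis genes were set against scaling, sequence trends and the seed word. Relative to the median of all tested genes, the replication list was at -0.171 ± 0.024 (SE) under quantile scaling, against -0.205 as deposited. The cholesterol list was at -0.243 ± 0.059, against -0.278, which argues against scaling as the whole cause of either. Scaling by 1 factor per library moves genes nearly alike and left the replication list between -0.205 and -0.202, so it could hardly have altered this difference. Under quantile scaling the mitosis list was at -0.088 ± 0.026, against -0.115 as deposited. It kept its call (camera, adjusted p = 0.000221; as deposited, adjusted p = 0.154 with an estimated correlation), which argues against scaling as its whole cause. Length and GC content went with the change across genes (9.57% of the variance), but after its removal the replication and cholesterol medians were at -0.25 or below and the mitosis median was -0.156 ± 0.029 (SE), against -0.155 before, which argues against that trend as the whole cause. Of 94 members searched, 7 carried GTTGGAA (odds ratio 0.65, interval 0.30 to 1.40), and the 87 members without it had a median of -0.235 ± 0.021 (SE), which argues against seed sites in the members themselves, while an action through a regulator with a site cannot be told apart from the effect of NUDT3.

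The changes of the 7 small nucleolar RNAs may rest on a few fragments on RNAs shorter than the sequenced fragments. Their values were whole multiples, within 1.5%, of the value of 1 fragment inferred for these short RNAs, with at most 8 fragments per library. Summed over 3 libraries, SNORA25 had 5 fragments in ConKD and 0 in Nudt3KD, SNORA44 had 4 and 0, SNORA24 had 5 and 1, SNORA4 had 8 and 2, SNORA2A had 8 and 3, SNORA61 had 15 and 7, and SNORA72 had 1 and 5. Counts this low leave open whether any of them differs.

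The rise of immediate early mRNAs, many of which decay through AU-rich elements, raised the hypothesis that mRNAs with such elements were higher in general. The 852 genes with the 9-base word TTATTTATT in the 3-prime UTR lay 0.012 ± 0.007 (SD over 1000 shuffles) above genes of similar UTR length without it. Among immediate early members the median was 0.25 for the 8 with the word and 0.32 for those without it. This argues against this word as the shared feature. Other AU-rich elements were not tested, and 8 of the 29 members searched carried the word. Removal of the length and GC trend took the median of the immediate early list from 0.320 to 0.206 ± 0.069 (SE) and that of the inflammation list from 0.570 to 0.428 ± 0.604.

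Splitting the 6 libraries into other groups of 3 gave at most 2 changed genes, against 2528 for the real groups, and 1 of the 10 splits, the real one, reached that count. For transcripts the highest other count was 2 against 860, and again 1 split reached it. For lists the other splits gave between 5 and 14, against 16, reached by 1 split, so lists also passed under every mixed grouping. Each other split mixes libraries of both groups, so part of the group difference stays and the rest widens the spread within groups. Such splits are not free of the difference, and their low gene counts are no measure of false calls. The 10 splits are too few for a share under 0.05.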
